A study of Mus musculus with 12 samples.

How the data were processed

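RNA was measured in 12 kidney cortex libraries of C57BL/6 mice by stranded mRNA sequencing, 3 in each of 4 labelled groups defined by disease (control or glomerulonephritis, GN) and drink (water or captopril). Groups were taken from the labels alone. The title numbers of the libraries were not read as mouse numbers, because the labels do not say whether a library is a pool.

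The authors deposited a table of expected counts, the estimated counts of reads per gene symbol before any scaling for depth, and a table of RPKM values. Per the submitters' processing notes Bowtie2 and Partek were used with the mm10 genome. Their versions, roles, annotation and filters are not given in the sources used here. The deposited estimated counts were whole numbers in most but not all entries, as when reads shared between features are divided, and they were rounded before testing. Paralogs and genes with shared exons (Mup genes, Hbb-b2 and Hbb-bt, Ugt1a2, and Ren2, which C57BL/6 mice lack) can therefore carry each other's reads. The deposited RPKM values were made by the authors from reads per kilobase and depth. The length implied by count over RPKM lay within 10% of the genomic span of the gene for 90.5% of 11451 genes compared with RefSeq (median ratio 1.06), so RPKM values were used for comparisons of 1 gene between libraries and not between genes. The count table held 24452 symbols while 24537 were in the RPKM data, with 24051 in both. Of the count symbols, 5604 had no count in any library. Coordinates came from the RefSeq annotation of the mouse GRCm38 assembly, which shares its coordinates with mm10, and 23275 symbols were found in it. That annotation need not be the one the authors used.

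Library totals were 14.2 to 22.8 M counts (M, mega). Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15, over the 4 groups), which left 14618. Counts were scaled by TMM and fitted with edgeR 4.0.16 quasi-likelihood models (R 4.3.3) with 1 mean per group over all 12 libraries, and p values were adjusted by Benjamini-Hochberg over all genes tested, at a threshold of 0.05. The SE of a log2 fold change was taken from its estimate and F statistic. CPM were computed by edgeR from library totals adjusted by TMM, and spreads are SD over 3 libraries. The adjusted p values of gene lists came from camera in limma 3.58.1, two-sided, with a preset correlation between genes of 0.01 and, as an alternative, an estimated correlation, adjusted over the 34 lists tested in a comparison. Lists with fewer than 3 tested genes were not tested, which left out the mitochondrially encoded genes. Beside the count over all genes, a count adjusted over the list alone is given. In the text, an adjusted p beside a gene is from edgeR and one beside a list is from camera. DESeq2 1.42.0 served as an alternative tool. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

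The 7 comparisons, their tests, the naming rule, the gene lists and the processing alternatives were chosen before the data were examined. These were GN_water against Control_water, GN_captopril against GN_water, Control_captopril against Control_water, GN_captopril against Control_captopril, the interaction, GN averaged over treatments and captopril averaged over disease. A further 2 comparisons, GN_water against Control_captopril and GN_captopril against Control_water, were chosen after the sex-linked markers had been seen, because each sets libraries with the same markers against each other. No library was regrouped or left out of the comparisons.

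The 35 lists held 668 symbols, of which 638 were in the count table. They were renin, angiotensin and kinin genes, aldosterone and distal transport, tubular injury, matrix and fibrosis, complement, macrophage and monocyte, T and natural killer cell, B and plasma cell, neutrophil, chemokine and cytokine, adhesion and NF-kappaB, interferon response, antigen presentation, acute phase, proximal tubule, distal nephron and collecting duct, podocyte, mesangial and smooth muscle, endothelial, fatty acid oxidation, nuclear oxidative phosphorylation, mitochondrially encoded, proliferation, oxidative stress and Nrf2, immediate early, circadian clock, unfolded protein response, androgen-induced kidney, female-biased kidney, Y-linked and Xist, fat, adrenal, pancreas and liver, blood and globin, and kidney medulla genes. Some genes stand in more than 1 list, such as Vcam1, Cybb, Acta2 and Il1b. Named genes were the 8 higher and the 8 lower with the largest change among those past the threshold with a mean of at least 1 CPM (and, between 2 groups, no overlap), up to 4 called members per list by smallest adjusted p or, where none passed, 2 by level, and a fixed set of 18 kidney genes. Predicted genes and immunoglobulin or T cell receptor segments were left out of the first part. The genes of the first part are named in the report, except that some genes that met the rule are not reported here. Of the list members that met the second part, only some are described, and names outside the rule are marked as chosen after their values were seen.

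The GN score of a library was the mean log2 CPM of the genes higher minus that of the genes lower in GN averaged over treatments, a comparison that is orthogonal to the interaction in this balanced design. Its group means were compared by exact permutation tests. The difference between the increments was tested by permuting treatment labels within controls and within GN.

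The tests were checked on simulated data made from these counts, in which 200 genes were changed. In GN_captopril against GN_water 67% of changes of 1.5-fold and 87% of 2-fold changes were found, with 3 false calls among 14591 genes. In GN averaged 75% and 90% were found, with 8 false calls among 14586 genes. With the complement list raised 1.5-fold, camera called that list and 2 others of 34, antigen presentation and adrenal genes, which had not been changed and share no gene with it.

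The alternatives were RLE size factors, no filter or at least 1 CPM in 6 libraries, DESeq2, a robust fit, a fit of only the groups compared, the title number as a block, a minimum absolute log2 fold change of 1, limma on log2 RPKM (pseudocount 0.5 with a minimum mean of 0.5, pseudocount 0.1, or no filter), other genes for the score, and leaving out each library in turn. Leaving out both libraries with the most adrenal marker counts was added after those counts had been seen. A count of 0 is reported with a floor of 3 counts over the group. Floors cover counting error only, since reads without molecular identifiers are not independent molecules, while SD and SE include variation between libraries.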

Results

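The data were 12 stranded mRNA sequencing libraries from the kidney cortex of C57BL/6 mice, all labelled adult male. They formed 4 groups of 3 libraries: control mice given water (Control_water), control mice given captopril (Control_captopril), mice with glomerulonephritis given water (GN_water) and mice with glomerulonephritis given captopril (GN_captopril). Glomerulonephritis (GN), inflammation of the kidney's filtering units, was induced by intraperitoneal horse spleen apoferritin, a foreign protein that forms immune complexes, at 10 mg on 5 days a week, with 100 micrograms of lipopolysaccharide 3 times a week, for 6 weeks. Controls received saline, and kidneys were taken at week 9. Captopril inhibits angiotensin-converting enzyme, and its dose was not in the labels. The title of each library carries a pair of consecutive numbers, and the labels did not say whether a library held 1 mouse or a pool. Total counts per library ran from 14.2 to 22.8 M. The mean was 19.0 ± 3.38 M in Control_water, 21.0 ± 1.31 M in Control_captopril, 20.6 ± 1.98 M in GN_water and 16.1 ± 2.29 M in GN_captopril (SD, n = 3 each). Count floors given for single genes cover counting error only.

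Sex-linked transcripts did not match the label male in 6 of the 12 libraries, and renin did not follow the captopril label in the controls. The libraries labelled Control_water and GN_captopril carried Y-linked transcripts, with Ddx3y, Kdm5d, Uty and Eif2s3y summing to between 121 and 144 CPM, and Xist at no more than 0.182 CPM. The libraries labelled Control_captopril and GN_water carried Xist, the RNA that silences an X chromosome in female cells (chromosome X, 103460373 to 103483233), at between 181 and 375 CPM, and the same 4 Y-linked genes together at no more than 0.101 CPM. Ren1, which encodes renin, the protease that starts the angiotensin cascade (chromosome 1, 133350674 to 133360320 of the mm10 assembly), is known to rise in the kidney when angiotensin-converting enzyme is inhibited. Its mean was 1339.9 ± 394 CPM in the libraries labelled Control_water and 74.8 ± 10.1 CPM in those labelled Control_captopril, with 543 ± 132 CPM in GN_captopril and 24.8 ± 4.90 CPM in GN_water (SD, n = 3 each). Ren1 was thus lower in the captopril-labelled than in the water-labelled controls (log2 fold change -4.16 ± 0.23 (SE), adjusted p = 2.37e-08, edgeR) and higher in the captopril-labelled than in the water-labelled GN libraries (log2 fold change 4.45 ± 0.24 (SE), adjusted p = 1.46e-08). Each of the 4 comparisons between groups that share a disease or a treatment label therefore set libraries with Y-linked transcripts against libraries with Xist. The average of both GN comparisons and the average of both captopril comparisons were balanced for these markers. Groups are named below as labelled, and no library was moved.

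**Figure D1:**
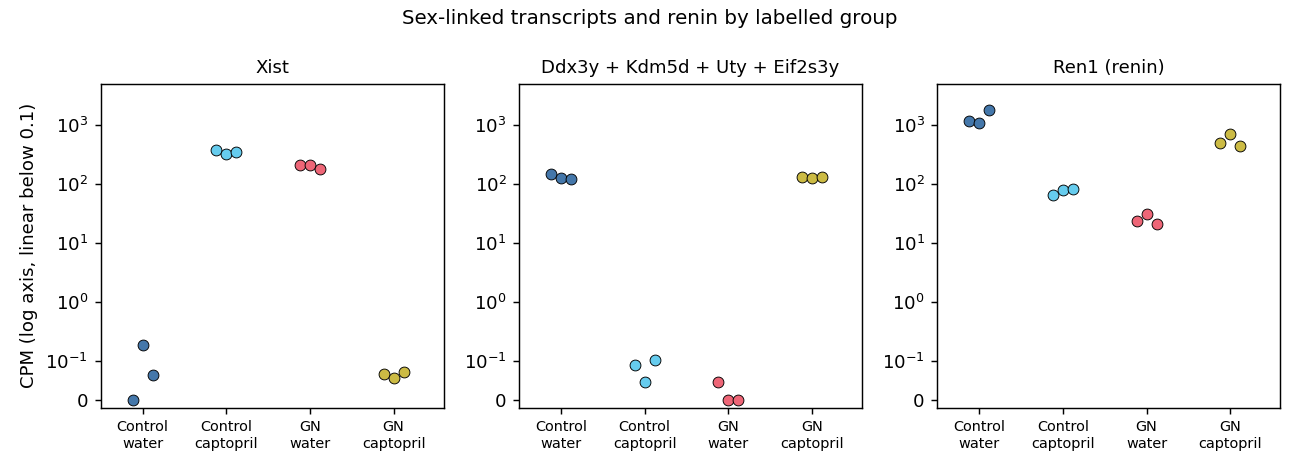
Each point is 1 library, grouped as labelled (3 per group): Xist, Y-linked transcripts (Ddx3y, Kdm5d, Uty and Eif2s3y summed) and Ren1, in CPM on log axes that are linear below 0.1. Libraries labelled Control_water and GN_captopril had 121 to 144 CPM of Y-linked transcripts, and those labelled Control_captopril and GN_water had 181 to 375 CPM of Xist.

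The 4 groups separated from one another without overlap in a principal component plot of log2 CPM, and the first component (45.9% of variance) followed the sex-linked markers as well as disease. Control_water lay between -46.3 and -42.8 on it, GN_captopril between -31.6 and -15.8, Control_captopril between 13.8 and 19.6 and GN_water between 48.3 and 54.9. The second component (28.5%) placed all 6 controls below all 6 GN libraries. Replicates of a group were alike (Spearman's rho between 0.991 and 0.996 across genes, which are not independent replicates), with counts dispersed beyond counting error (chi-squared per degree of freedom between 5.64 and 15.6). Transcripts of the adrenal cortex, a gland that lies on the kidney, were present in some captopril-labelled libraries. The genes of a fixed adrenal list (steroid hormone synthesis and its regulation), Akr1b7 left out because kidney cells that make renin also express it, summed to 5340 counts in Control_captopril replicate 3, 1271 in GN_captopril replicate 3 and 275 in GN_captopril replicate 2, against 16 to 98 in the other 9 libraries. Star, which carries cholesterol into mitochondria for steroid synthesis, averaged 37.7 ± 62.1 CPM in Control_captopril and 16.8 ± 22.0 in GN_captopril, against 0.961 ± 0.0737 in Control_water and 0.769 ± 0.328 in GN_water (SD, n = 3 each). Adipoq, an adipocyte hormone named here after its values were seen, varied within groups, from 0 to 35.5 CPM in GN_captopril.

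**Figure D2:**
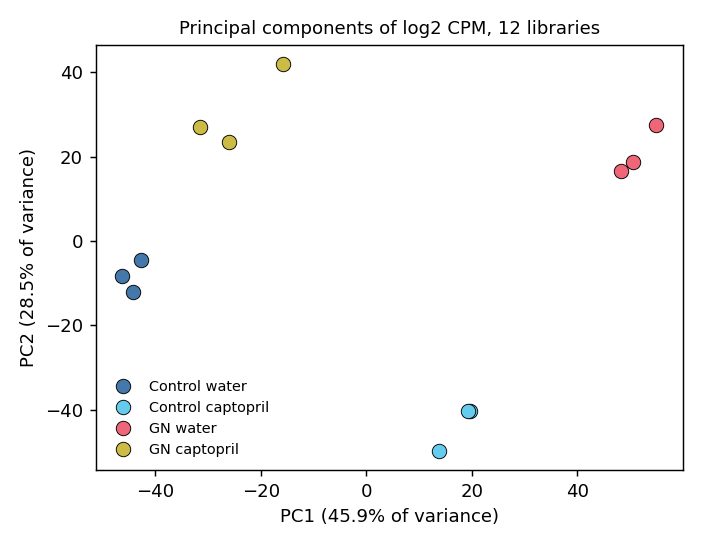
First and second principal components of log2 CPM, 1 point per library, coloured by labelled group. The first component explains 45.9% and the second 28.5% of the variance, and all 6 GN libraries lie above all 6 controls on the second.

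Averaged over both treatment labels, GN raised transcripts of immune cells, adhesion molecules and extracellular matrix in the kidney cortex and lowered transcripts of tubular metabolism. This comparison asks what the disease model changed, and it is the one in which the sex-linked markers were balanced and which does not depend on which control group had captopril. Of 14618 genes tested, 2378 were higher and 2138 lower in GN, 782 and 31 of them by at least 2-fold (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05, 6 libraries against 6). Vcam1, the adhesion molecule that binds circulating leukocytes (chromosome 3, 116110020 to 116129688), had 12 ± 1.56 and 13.9 ± 1.75 CPM in Control_water and Control_captopril, 67.0 ± 4.63 in GN_water and 32.9 ± 2.22 in GN_captopril (SD, n = 3 each; log2 fold change 1.86 ± 0.07 (SE), adjusted p = 3.01e-08). Lyz2, the lysozyme of macrophages (chromosome 10, 117277541 to 117282272), had 32.6 ± 1.20, 30.9 ± 9.38, 715 ± 144 and 372 ± 194 CPM in the same order (log2 fold change 4.02 ± 0.23 (SE), adjusted p = 3.56e-07).

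Immune cell markers rose together. Among the macrophage and monocyte genes 21 of 22 were higher and 0 lower (21 and 0 adjusted over the list alone, camera adjusted p = 2.00e-46). They included Adgre1, which encodes the F4/80 antigen (log2 fold change 2.78 ± 0.21, SE), the membrane protein gene Ms4a7 (2.93 ± 0.18) and Cx3cr1, the fractalkine receptor (1.53 ± 0.07). Of the T and natural killer cell genes 19 of 20 were higher and 0 lower (19 and 0 adjusted over the list alone, camera adjusted p = 3.62e-22). They included Cd3g, a chain of the T cell receptor complex (2.28 ± 0.17), Cd4 (2.82 ± 0.22), the kinase Lck (1.48 ± 0.13) and Nkg7 (2.38 ± 0.25). B and plasma cell genes rose as well: 9 of 10 were higher and 0 lower (9 and 0 adjusted over the list alone, camera adjusted p = 1.48e-11, and adjusted p = 0.0724 with an estimated correlation). Jchain, which joins secreted IgA and IgM (chromosome 5, 88519809 to 88527897), changed by 5.49 ± 0.41 and the B cell receptor regulator Cd22 by 2.63 ± 0.25 on the log2 scale. In the neutrophil list 7 of 7 were higher and 0 lower (7 and 0 adjusted over the list alone, camera adjusted p = 4.80e-08). They included Csf3r, the receptor for granulocyte colony-stimulating factor, at 2.40 ± 0.19 and S100a8 at 2.02 ± 0.35. Chemokine and cytokine genes followed: 27 of 30 were higher and 0 lower (27 and 0 adjusted over the list alone, camera adjusted p = 1.29e-27). Ccl8 changed by 6.32 ± 0.50, Ccl2, the main attractant of monocytes, by 3.05 ± 0.25, and Il1b by 1.92 ± 0.14. Among adhesion and NF-kappaB target genes 17 of 18 were higher and 0 lower (17 and 0 adjusted over the list alone, camera adjusted p = 1.23e-35). They included Icam1 (0.90 ± 0.06), Tlr2 (1.78 ± 0.13) and Birc3 (1.01 ± 0.06). Of the antigen presentation genes 23 of 23 were higher and 0 lower (23 and 0 adjusted over the list alone, camera adjusted p = 3.23e-25, and adjusted p = 0.0597 with an estimated correlation). They included the class II genes H2-Eb1 (1.38 ± 0.12) and Cd74 (1.48 ± 0.14). Of the interferon response genes 31 of 37 were higher and 0 lower (33 and 0 adjusted over the list alone, camera adjusted p = 1.21e-14, and adjusted p = 0.125 with an estimated correlation). They included Gbp2 at 1.55 ± 0.18 and Bst2 at 0.94 ± 0.11.

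The genes with the largest changes were expressed near zero in controls. Marco, a scavenger receptor of macrophages, averaged 0.0202 and 0.0640 CPM in Control_water and Control_captopril, 35.2 ± 36.1 in GN_water and 8.51 ± 11.4 in GN_captopril (SD, n = 3). Irg1, the older symbol of Acod1, which makes itaconate in activated macrophages, averaged 0.0215 and 0.0322 CPM in the controls, 6.45 ± 2.12 in GN_water and 3.53 ± 2.02 in GN_captopril. Fpr1, the formyl peptide receptor of phagocytes, averaged 0.0370 and 0.0640 CPM in the controls, 8.68 ± 2.22 in GN_water and 3.99 ± 1.69 in GN_captopril. The controls held 1 to 4 counts of each of these 3 genes per group, so no fold is given. Saa3, an acute phase protein made in inflamed tissue, varied within the GN groups, from 21.6 to 151 CPM in GN_water and from 2.13 to 57.7 CPM in GN_captopril, against means of 0.0370 and 0.390 CPM in the controls.

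Genes of extracellular matrix, tubular injury, complement and the acute phase rose with the immune lists. Of the matrix and fibrosis genes 32 of 39 were higher and 0 lower (34 and 0 adjusted over the list alone, camera adjusted p = 1.59e-28). Col1a1 (chromosome 11, 94936224 to 94953042) and Col3a1, the main fibrillar collagens, changed by 1.12 ± 0.09 and 1.32 ± 0.11 on the log2 scale (SE), and Tnc, a matrix protein of wounds, by 1.32 ± 0.09. In the tubular injury list 13 of 24 were higher and 0 lower (14 and 0 adjusted over the list alone, camera adjusted p = 9.15e-14). Havcr1, which encodes kidney injury molecule 1 (chromosome 11, 46739822 to 46779578), had 2.74 ± 0.521, 2.46 ± 1.76, 24.5 ± 2.90 and 7.94 ± 1.55 CPM in Control_water, Control_captopril, GN_water and GN_captopril (log2 fold change 2.41 ± 0.23 (SE), adjusted p = 6.69e-06). Lcn2, the iron-carrier-binding lipocalin released by injured tubules (chromosome 2, 32384637 to 32387739), had 4.61 ± 0.713, 1.99 ± 0.292, 27.5 ± 6.11 and 6.22 ± 3.23 CPM (log2 fold change 2.10 ± 0.21 (SE), adjusted p = 1.08e-05). Timp1, an inhibitor of matrix proteases, changed by 2.94 ± 0.24 and Cd44, a hyaluronan receptor, by 2.17 ± 0.19. Of the complement genes 17 of 24 were higher and 0 lower (17 and 0 adjusted over the list alone, camera adjusted p = 4.27e-18). They included C3ar1, the receptor of the C3a fragment, at 2.40 ± 0.14 and C1qa at 2.11 ± 0.17. Of the acute phase genes 12 of 17 were higher and 1 lower (12 and 1 adjusted over the list alone, camera adjusted p = 3.12e-09). They included Serpina3g at 3.28 ± 0.22 and Lbp, the binding protein of lipopolysaccharide, at 1.26 ± 0.09. Proliferation genes included Mki67 (1.49 ± 0.19) and Top2a (1.59 ± 0.22), and of the list 23 of 26 were higher and 1 lower (24 and 1 adjusted over the list alone, camera adjusted p = 4.80e-08, and adjusted p = 0.221 with an estimated correlation). Immediate early genes included Egr2 (2.08 ± 0.28) and Atf3 (1.19 ± 0.14), and of the list 12 of 19 were higher and 0 lower (12 and 1 adjusted over the list alone, camera adjusted p = 0.00106, and adjusted p = 0.235 with an estimated correlation).

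**Figure D3:**
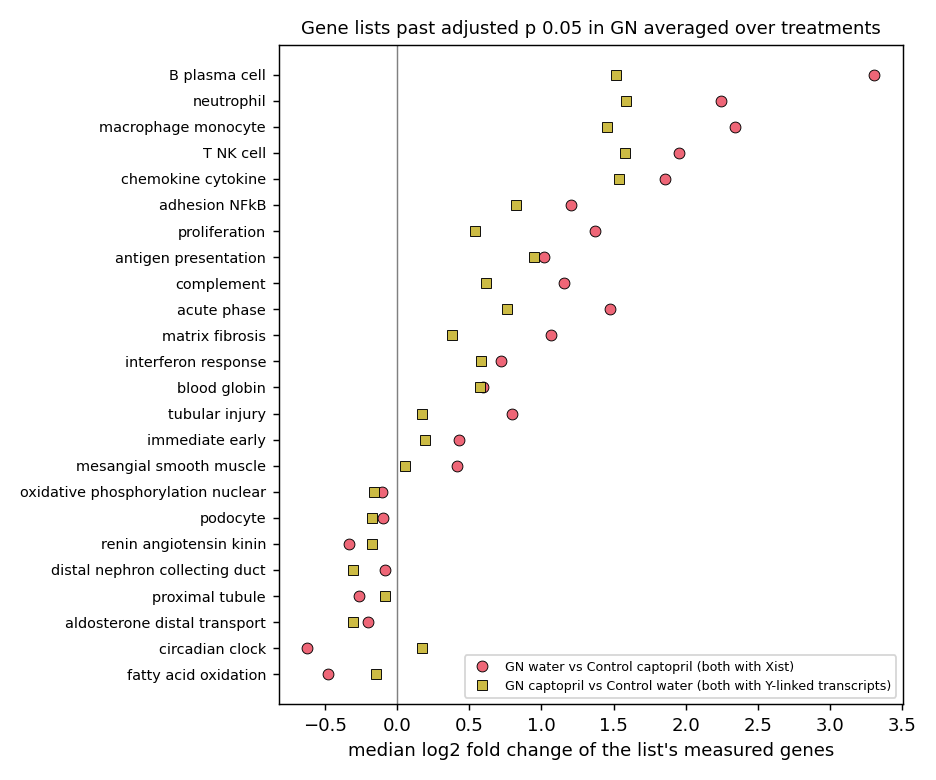
Median log2 fold change of the measured members of each gene list fixed before the data were examined, for GN_water against Control_captopril (circles, both with Xist) and GN_captopril against Control_water (squares, both with Y-linked transcripts). The lists shown passed the camera test in GN averaged over treatments, and the macrophage and monocyte medians were 2.34 and 1.46.

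Genes of energy metabolism and of differentiated tubule segments were lower in GN. Of the fatty acid oxidation genes 0 of 30 were higher and 26 lower (0 and 29 adjusted over the list alone, camera adjusted p = 1.15e-15). They included Acaa1b, a peroxisomal thiolase, at -0.68 ± 0.08 and Hadh at -0.30 ± 0.03 (log2 fold change ± SE). Nuclear genes of oxidative phosphorylation changed less in size, with a median of -0.12, and 0 of 34 were higher and 19 lower (0 and 24 adjusted over the list alone, camera adjusted p = 4.01e-06, and adjusted p = 0.283 with an estimated correlation). Sdha, a subunit of succinate dehydrogenase, was among those lower (-0.26 ± 0.04). In the proximal tubule list 2 of 33 were higher and 17 lower (2 and 19 adjusted over the list alone, camera adjusted p = 2.02e-06, and adjusted p = 0.0923 with an estimated correlation). Pck1 and G6pc, enzymes of gluconeogenesis, changed by -0.89 ± 0.13 and -0.53 ± 0.07, and Hnf4a, a transcription factor of proximal tubule identity, by -0.32 ± 0.04. Among distal nephron and collecting duct genes 2 of 20 were higher and 10 lower (2 and 11 adjusted over the list alone, camera adjusted p = 3.39e-04). Pvalb (-1.97 ± 0.21), Calb1 (-0.72 ± 0.12) and Slc12a3, the thiazide-sensitive sodium chloride cotransporter (-0.61 ± 0.08), all mark the distal convoluted tubule. Of the aldosterone-regulated transport genes 0 of 14 were higher and 9 lower (0 and 9 adjusted over the list alone, camera adjusted p = 4.75e-05). They included Scnn1a, a subunit of the epithelial sodium channel (-0.44 ± 0.05). In the renin, angiotensin and kinin list 0 of 13 were higher and 6 lower (0 and 8 adjusted over the list alone, camera adjusted p = 0.00276, and adjusted p = 0.0597 with an estimated correlation). Ren1 was lower in GN (log2 fold change -1.45 ± 0.15 (SE), adjusted p = 1.45e-05), as was the kallikrein gene Klk1 (-0.25 ± 0.05). Agt had a log2 fold change of -0.03 ± 0.07 and Agtr1a of 0.02 ± 0.04, neither past the threshold (adjusted p = 0.74 and 0.726). Mmp13, a collagenase, was also lower (log2 fold change -2.67 ± 0.22 (SE), adjusted p = 2.16e-06).

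Markers of glomerular and vascular cells went both ways. Of the podocyte genes 2 of 24 were higher and 10 lower (2 and 11 adjusted over the list alone, camera adjusted p = 0.0268, and adjusted p = 0.509 with an estimated correlation). Wt1, a transcription factor of podocytes, was lower (-0.45 ± 0.09, log2 fold change ± SE). The podocyte list lost its call without Control_water replicate 1, GN_captopril replicate 3 or GN_water replicate 3, with adjusted p = 0.0848, 0.0614 and 0.0788, and without both libraries with the most adrenal marker counts. In the mesangial and smooth muscle list 7 of 15 were higher and 2 lower (7 and 2 adjusted over the list alone, camera adjusted p = 0.0179, and adjusted p = 0.387 with an estimated correlation), and this call was lost without GN_captopril replicate 2 (adjusted p = 0.0745). Of the blood and globin genes 8 of 9 were higher and 0 lower (8 and 0 adjusted over the list alone, camera adjusted p = 0.00276, and adjusted p = 0.381 with an estimated correlation). Of the circadian clock genes 0 of 17 were higher and 10 lower (0 and 10 adjusted over the list alone, camera adjusted p = 0.00206, and adjusted p = 0.0832 with an estimated correlation). This average joined unlike pairs: clock genes gave 4 higher and 10 lower in GN_water against Control_captopril, and 6 higher and 3 lower in GN_captopril against Control_water, where the list was not called (adjusted p = 0.101, and 0.0471 upward without GN_water replicate 3). The other lists were not called: among endothelial genes 7 of 18 were higher and 3 lower (9 and 3 adjusted over the list alone, camera adjusted p = 0.305), oxidative stress and Nrf2 genes 3 of 19 were higher and 8 lower (3 and 9 adjusted over the list alone, camera adjusted p = 0.147), a list that was called without Control_water replicate 1 (adjusted p = 0.0418), and unfolded protein response genes 1 of 16 were higher and 2 lower (1 and 2 adjusted over the list alone, camera adjusted p = 0.767). For markers of neighbouring tissue, fat genes gave 0 higher and 0 lower of 9 (0 and 0 adjusted over the list alone, camera adjusted p = 0.851), adrenal genes 0 higher and 1 lower of 5 (0 and 0 adjusted over the list alone, camera adjusted p = 0.851), pancreas and liver genes 0 higher and 0 lower of 5 (0 and 0 adjusted over the list alone, camera adjusted p = 0.851) and kidney medulla genes 2 higher and 1 lower of 8 (2 and 1 adjusted over the list alone, camera adjusted p = 0.34). Sex-linked and sex-biased lists gave no call either. Y-linked genes and Xist gave 0 higher and 0 lower of 5, and female-biased genes 0 and 0 of 4. Adjusted over the list alone these were the same (camera adjusted p = 0.759 and 0.861). Androgen-induced genes gave 4 higher and 1 lower of 8 (4 and 1 adjusted over the list alone, camera adjusted p = 0.167). The 15 mitochondrially encoded genes of a further list were absent from the count table. Between 3907 and 4564 genes were called when any 1 library was left out, and 2142 with limma on the deposited RPKM values in place of counts. Which direction had more genes was not stable: it was 2040 higher and 2318 lower, 2007 and 2171, and 2101 and 2341 without GN_water replicates 1, 2 and 3, 2324 and 2338 with RLE size factors, 2230 and 2300 with DESeq2, and 1489 and 653 with limma on RPKM.

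Comparing groups with the same sex-linked markers, a choice made after these markers had been seen, gave immune and injury lists called upward in both pairs at the preset correlation, with more genes past the threshold in the pair that carried Xist. Between GN_water and Control_captopril 2476 genes were higher and 1930 lower (1082 and 76 by at least 2-fold), and between GN_captopril and Control_water 1031 were higher and 734 lower (422 and 28). These comparisons cross the treatment labels, so disease and labelled treatment cannot be separated within either one. The sets shared 738 higher genes, against 175 expected if they were independent, and 252 lower genes, against 96.9, while 80 genes were called in opposite directions. The log2 fold changes correlated across genes, which are not independent replicates (Pearson's r = 0.554, Spearman's rho = 0.399). Timp1 changed by 3.49 ± 0.32 in the pair with Xist and by 2.39 ± 0.35 in the pair with Y-linked transcripts (log2 fold change ± SE), Ccl2 by 3.22 ± 0.34 and 2.88 ± 0.38, Cd4 by 3.26 ± 0.29 and 2.38 ± 0.33, and Serpina3g by 3.25 ± 0.28 and 3.31 ± 0.33. Lcn2 changed by 3.78 ± 0.29 in the first pair (adjusted p = 2.88e-06) and did not pass in the second (0.42 ± 0.30, adjusted p = 0.391). Col1a1 likewise changed by 1.89 ± 0.12 (adjusted p = 1.12e-06) and had 0.35 ± 0.12 in the second (adjusted p = 0.0758). The difference between the pairs, tested as captopril averaged over control and GN, passed for Lcn2 (adjusted p = 0.00104) and for Col1a1 (adjusted p = 5.33e-04). Ren1 was lower in GN within both pairs, with log2 fold changes of -1.59 ± 0.22 and -1.30 ± 0.20 (adjusted p = 1.60e-04 and 0.00178).

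With an estimated correlation the calls of the B and plasma cell, interferon response and antigen presentation lists were lost in both pairs (adjusted p = 0.0857, 0.207 and 0.1 in the pair with Xist, and 0.186, 0.177 and 0.0984 in the other). Those of complement and acute phase genes were lost in the pair with Y-linked transcripts (adjusted p = 0.0984 each with an estimated correlation). Macrophage and monocyte genes gave 21 higher and 0 lower of 22 (21 and 0 adjusted over the list alone, camera adjusted p = 4.44e-37) in the pair with Xist and 19 higher and 0 lower of 22 (19 and 0 adjusted over the list alone, camera adjusted p = 7.39e-32) in the pair with Y-linked transcripts. Matrix genes gave 34 higher and 0 lower of 39 (34 and 0 adjusted over the list alone, camera adjusted p = 3.05e-32) and 13 higher and 0 lower of 39 (17 and 1 adjusted over the list alone, camera adjusted p = 2.08e-10, and adjusted p = 0.0984 with an estimated correlation). Fatty acid oxidation genes gave 0 higher and 28 lower of 30 (0 and 28 adjusted over the list alone, camera adjusted p = 9.85e-20) and 0 higher and 8 lower of 30 (0 and 10 adjusted over the list alone, camera adjusted p = 1.95e-04, and adjusted p = 0.183 with an estimated correlation). Cpt1a, which admits long-chain fatty acids to mitochondria, changed by -0.67 ± 0.06 in the first pair, and Acaa1b by -0.68 ± 0.12 in the second. Dbp, a clock-controlled transcription factor, changed in opposite directions, by -2.42 ± 0.16 in the pair with Xist and by 1.29 ± 0.14 in the pair with Y-linked transcripts. The count for GN_captopril against Control_water fell to 968 without GN_captopril replicate 3, to 975 without Control_water replicate 2, and to 938 without both libraries with the most adrenal marker counts, an alternative chosen after those counts were seen. It was 951 when the fit held only these 6 libraries, and limma on the deposited RPKM values called 930 genes in this pair and 2342 in the pair with Xist. In the pair with Xist more genes were lower than higher without GN_water replicates 1, 2 and 3 (1863 higher and 2199 lower, 1744 and 1982, and 1889 and 2143).

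The comparison of GN with control under water asks for the effect of the disease without the drug. The libraries labelled GN_water had 4000 genes higher and 3491 lower than those labelled Control_water, 1555 and 390 by at least 2-fold. Sex-linked and androgen-induced genes were among the largest differences. Xist was 201 CPM in GN_water and 0.0822 CPM in Control_water, and Slco1a1, an androgen-induced organic anion transporter of the kidney, was 0.0576 and 232 ± 65.1 CPM (SD, n = 3). All 8 androgen-induced genes were lower (camera adjusted p = 8.00e-48, and 8 adjusted over the list alone), and this comparison alone does not separate disease from the sex-linked markers. The immune lists were called upward at the preset correlation, and most of these calls were lost with an estimated one. Of the T and natural killer cell genes 20 of 20 were higher and 0 lower (20 and 0 adjusted over the list alone, camera adjusted p = 7.59e-08, and adjusted p = 0.202 with an estimated correlation). Of the antigen presentation genes 23 of 23 were higher and 0 lower (23 and 0 adjusted over the list alone, camera adjusted p = 1.87e-08, and adjusted p = 0.296 with an estimated correlation), of the interferon genes 35 of 37 were higher and 0 lower (36 and 0 adjusted over the list alone, camera adjusted p = 9.79e-10, and adjusted p = 0.269 with an estimated correlation). With an estimated correlation the macrophage, neutrophil, chemokine, B and plasma cell, complement and acute phase calls were also lost (adjusted p = 0.153, 0.216, 0.154, 0.296, 0.206 and 0.181), and the adhesion and NF-kB list kept its call (0.0443). Of the matrix genes 37 of 39 were higher and 0 lower (38 and 0 adjusted over the list alone, camera adjusted p = 4.18e-16, and adjusted p = 0.0649 with an estimated correlation). In the tubular injury list 19 of 24 were higher and 1 lower (19 and 1 adjusted over the list alone, camera adjusted p = 2.41e-10). They included Havcr1 at 3.17 ± 0.31, Lcn2 at 2.59 ± 0.27 and Spp1, which encodes osteopontin, at 2.09 ± 0.09 (log2 fold change ± SE). Proximal tubule genes gave 4 higher and 19 lower of 33 (4 and 20 adjusted over the list alone, camera adjusted p = 7.96e-15), and distal nephron genes gave 13 higher and 1 lower of 20 (13 and 1 adjusted over the list alone, camera adjusted p = 0.00398, and adjusted p = 0.093 with an estimated correlation), against the direction of the averaged comparison. Ren1 fell by 5.75 ± 0.25 on the log2 scale (adjusted p = 2.24e-09). Between 6692 and 7661 genes were called without any 1 library, and 4713 with limma on the deposited RPKM values. More genes were lower than higher without GN_water replicates 1, 2 and 3 (3287 higher and 3631 lower, 3197 and 3495, and 3316 and 3591) and with DESeq2 (3563 and 3703), and limma on RPKM gave 3508 and 1205.

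The comparison of GN with control under captopril asks for the effect of the disease in treated mice. The libraries labelled GN_captopril had 2998 genes higher and 2815 lower than those labelled Control_captopril, 829 and 437 by at least 2-fold, with the sex-linked markers now in the opposite direction. All 8 androgen-induced genes were higher (8 adjusted over the list alone, camera adjusted p = 1.06e-67). Immune lists were called upward in part, at the preset correlation only. Of the macrophage and monocyte genes 19 of 22 were higher and 0 lower (21 and 0 adjusted over the list alone, camera adjusted p = 1.05e-08). Of the chemokine and cytokine genes 22 of 30 were higher and 1 lower (24 and 2 adjusted over the list alone, camera adjusted p = 1.37e-05). The T and natural killer cell, B and plasma cell, neutrophil, adhesion and NF-kB, antigen presentation and complement lists were also called upward. With an estimated correlation all these calls were lost (adjusted p = 0.358, 0.358, 0.358, 0.611, 0.358, 0.358, 0.566 and 0.494 in that order). Interferon genes, 10 of 37 higher and 3 lower, and acute phase genes, 9 of 17 higher and 2 lower, were not called as lists (camera adjusted p = 0.265 and 0.0618). The interferon list was called without GN_captopril replicate 2 (adjusted p = 0.0143) and the acute phase list without GN_captopril replicates 1 or 2 (0.0241 and 0.0158). Ccl2 changed by 2.57 ± 0.35 and Vcam1 by 1.24 ± 0.11 (log2 fold change ± SE). Distal nephron genes gave 0 higher and 14 lower of 20 (0 and 14 adjusted over the list alone, camera adjusted p = 1.72e-12) and podocyte genes 0 higher and 18 lower of 24 (0 and 18 adjusted over the list alone, camera adjusted p = 2.25e-05, and adjusted p = 0.358 with an estimated correlation). They included Nphs1 at -0.93 ± 0.14. In the pair with Xist 3 podocyte genes were higher and 4 lower (camera adjusted p = 0.276). In the pair with Y-linked transcripts 1 and 4 were (0.00187, preset correlation only). The proximal tubule list was called upward (median -0.08, mean 0.43), with 12 of 33 higher and 15 lower (13 and 15 adjusted over the list alone, camera adjusted p = 7.77e-04, and adjusted p = 0.358 with an estimated correlation). Slc7a13, which is androgen-induced, changed by 8.97 ± 0.13. Genes called in both GN comparisons were mostly in opposite directions, 2875 of them, while 767 were higher in both, against 820 expected if independent, and 187 lower in both, against 672. Log2 fold changes of these comparisons had Pearson's r = -0.228 (Spearman's rho = -0.235) across genes, which are not independent replicates. Between 4830 and 6182 genes were called without any 1 library. With limma on RPKM, more were lower (2378) than higher (1528).

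The series asks whether inhibition of angiotensin-converting enzyme reduces interstitial injury in chronic GN, which is the comparison of GN_captopril with GN_water. The libraries labelled GN_captopril had the tubular injury list called downward against those labelled GN_water, and the matrix list at the preset correlation only, and they also differed in sex-linked markers. Immune lists were called in part. In all, 2869 genes were higher and 3725 lower, 371 and 660 by at least 2-fold. Lcn2 and Havcr1 (means above) changed by -2.17 ± 0.26 and -1.64 ± 0.28 (log2 fold change ± SE, adjusted p = 2.62e-05 and 4.14e-04). Spp1, Vcam1 and Col1a1 changed by -2.06 ± 0.09, -1.03 ± 0.10 and -0.89 ± 0.12. Spp1 averaged 870, 2460, 3707 and 888 CPM in Control_water, Control_captopril, GN_water and GN_captopril, so it also differed between the control groups. In the tubular injury list 0 of 24 were higher and 18 lower (2 and 19 adjusted over the list alone, camera adjusted p = 1.35e-06). Of the matrix genes 0 of 39 were higher and 34 lower (0 and 34 adjusted over the list alone, camera adjusted p = 1.31e-08, and adjusted p = 0.22 with an estimated correlation). Of the macrophage and monocyte genes 0 of 22 were higher and 19 lower (0 and 19 adjusted over the list alone, camera adjusted p = 4.97e-04, and adjusted p = 0.64 with an estimated correlation). They included Cx3cr1 at -0.74 ± 0.09. Of the interferon genes 0 of 37 were higher and 22 lower (1 and 25 adjusted over the list alone, camera adjusted p = 0.00479, and adjusted p = 0.714 with an estimated correlation). T and natural killer cell genes were not called as a list: 0 of 20 were higher and 6 lower (0 and 4 adjusted over the list alone, camera adjusted p = 0.132, and 0.0392 without GN_water replicate 1). Chemokine and cytokine genes (camera adjusted p = 0.0559), antigen presentation genes (0.197), acute phase genes (0.0505) and neutrophil genes (0.607) were not called either. All of these but the neutrophil list were called without GN_captopril replicate 3 (adjusted p = 0.00261, 0.00258 and 0.00478). The chemokine list was also called without Control_captopril replicates 1 or 2 or any GN_water replicate (adjusted p = 0.0234 to 0.0381), and the acute phase list without Control_water replicates 2 or 3, Control_captopril replicates 1 or 3 or GN_water replicates 1 or 3 (0.0209 to 0.0422). Complement genes were called downward (camera adjusted p = 0.0298, adjusted p = 0.714 with an estimated correlation), a call lost without Control_water replicate 3 or GN_captopril replicates 1 or 2 (adjusted p = 0.0533, 0.108 and 0.0618). C3, Ccl2 and Cxcl1 did not pass (-0.90 ± 0.46, -0.66 ± 0.28 and -0.63 ± 0.37, adjusted p = 0.123, 0.0713 and 0.177). C3 passed without GN_captopril replicate 3 (log2 fold change -2.01), and Ccl2 without Control_water replicate 2, Control_captopril replicate 1 or Control_captopril replicate 2 (-0.66 each). Both also passed with limma on the deposited RPKM values. Proximal tubule genes gave 17 higher and 5 lower of 33 (18 and 7 adjusted over the list alone, camera adjusted p = 2.27e-12). They included the androgen-induced Slc7a13 (8.42 ± 0.13) and the organic anion transporter Slc22a6 (1.58 ± 0.09). Distal nephron genes gave 0 higher and 16 lower of 20 (0 and 16 adjusted over the list alone, camera adjusted p = 3.31e-07), and all 8 androgen-induced genes were higher (8 adjusted over the list alone, camera adjusted p = 3.74e-63). Clock genes gave 10 higher and 3 lower of 17 (11 and 4 adjusted over the list alone, camera adjusted p = 1.35e-06). They included Dbp at 3.81 ± 0.16 and Per3 at 2.44 ± 0.13. Between 5440 and 6935 genes were called without any 1 library. More genes were higher than lower without GN_water replicates 1, 2 and 3 (3076 higher and 2742 lower, 2900 and 2540, and 2994 and 2680) and with only these 6 libraries in the fit (3398 and 3047), and limma on RPKM gave 1311 and 3419.

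A GN score per library, the mean log2 CPM of the 2378 genes higher in GN averaged minus that of the 2138 genes lower, placed GN_captopril between the controls and GN_water. The score was -3.56 ± 0.09 in Control_water, -3.59 ± 0.12 in Control_captopril, -2.22 ± 0.10 in GN_water and -2.69 ± 0.20 in GN_captopril (SD, n = 3 each). GN_captopril was lower than GN_water by a difference of -0.48, with no overlap between libraries (exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 allows). The difference was -1.15 with genes chosen from GN_water against Control_water and 0.84 with genes chosen from GN_captopril against Control_captopril. Each of these sets was chosen on 1 of the groups compared, which favours a higher score in that group. Each was also chosen between groups with different sex-linked markers, which run in opposite directions in these comparisons. Between them 2875 genes were called in opposite directions. The opposite signs of the score therefore do not test the direction. Within the groups with the same sex-linked markers, the score rose by 1.38 from Control_captopril to GN_water and by 0.863 from Control_water to GN_captopril, 62.7% of the first. The difference between these increments was -0.51 (exact permutation of treatment labels within controls and within GN, two-sided, 400 assignments, p = 0.035), and the comparison was chosen after the sex-linked markers had been seen. Of the 4516 genes in the score, 73.5% had a smaller GN effect in the pair of GN_captopril and Control_water than in the other pair, with median log2 fold changes of 0.27 and 0.42 after each gene was given the sign of its averaged effect.

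**Figure D4:**
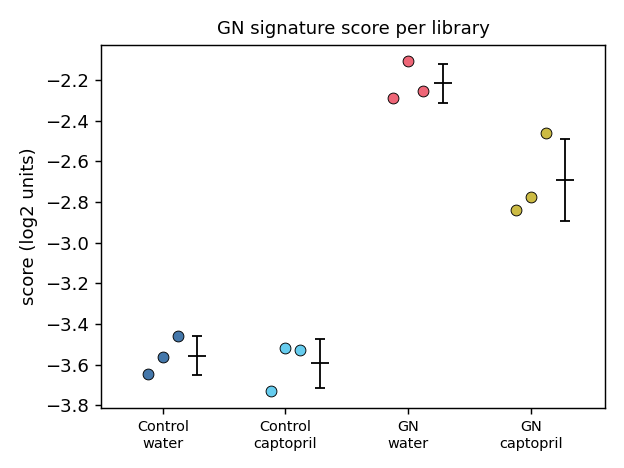
GN score of each library (mean log2 CPM of genes higher in GN minus that of genes lower), 1 point per library with the group mean and SD (n = 3), groups as labelled. GN_captopril averages -2.69 and GN_water -2.22, and both control groups lie below -3.4.

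The comparison of captopril with water in control mice asks for the effect of the drug without disease. The libraries labelled Control_captopril had 2247 genes higher and 2484 lower than those labelled Control_water, 368 and 352 by at least 2-fold, and markers of immune cells were not called. Macrophage and monocyte genes gave 1 higher and 0 lower of 22, and T and natural killer cell genes 0 and 0 of 20. Adjusted over the list alone these were the same (camera adjusted p = 0.971 and 0.938). Sex-linked and androgen-induced genes were among the largest differences. Xist was 345 ± 30.2 CPM in Control_captopril and 0.0822 CPM in Control_water, and Slco1a1 was 0 and 232 ± 65.1 CPM (SD, n = 3). A count of 0 over the 3 Control_captopril libraries allows up to 3 counts, or 0.0470 CPM. All 8 androgen-induced genes were lower (8 adjusted over the list alone, camera adjusted p = 5.22e-74). Ren1 was lower (values above), the opposite of what captopril is known to do, and this conflict with the labels applies to every direction here. Distal nephron genes gave 13 higher and 0 lower of 20 (13 and 2 adjusted over the list alone, camera adjusted p = 8.80e-08). They included Pvalb at 36.9 ± 2.85 CPM against 1.06 ± 0.236. Proximal tubule genes gave 10 higher and 14 lower of 33 (10 and 14 adjusted over the list alone, camera adjusted p = 2.10e-07, and adjusted p = 0.192 with an estimated correlation). Aldosterone-regulated transport genes gave 9 higher and 0 lower of 14 (10 and 0 adjusted over the list alone, camera adjusted p = 0.00129, and adjusted p = 0.0817 with an estimated correlation). Interferon response genes gave 6 higher and 0 lower of 37 (5 and 0 adjusted over the list alone, camera adjusted p = 0.0186, and adjusted p = 0.992 with an estimated correlation), a call that was lost without Control_captopril replicate 2 (adjusted p = 0.0983). Adrenal genes gave 4 higher and 0 lower of 5 (4 and 0 adjusted over the list alone, camera adjusted p = 0.632), with the counts in Control_captopril replicate 3 given above. Between 3863 and 4885 genes were called without any 1 library. With limma on RPKM, more were higher (2432) than lower (1114).

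Whether the drug effect depended on disease was asked with the interaction of GN and captopril, which in these libraries equals the sex-marker contrast doubled. It called 3444 genes higher and 3962 lower. All 8 androgen-induced genes were higher (8 adjusted over the list alone, camera adjusted p = 1.41e-75), and Ren1 had a log2 difference of 8.61 ± 0.33 (SE, adjusted p = 2.40e-10). Distal nephron genes gave 0 higher and 15 lower of 20 (0 and 15 adjusted over the list alone, camera adjusted p = 2.48e-08). Captopril averaged over control and GN was balanced for sex-linked markers. This contrast equals the difference, divided by 2, between the GN effects of the marker-matched pairs. A captopril effect cannot be told here from a GN response that differs with the markers. The contrast called 464 genes higher and 488 lower, 15 and 24 by at least 2-fold. The tubular injury list was called downward, the fatty acid oxidation and clock lists upward, and the matrix list downward at the preset correlation only. Lcn2, Col1a1 and Vcam1 changed by -1.68 ± 0.21, -0.77 ± 0.09 and -0.41 ± 0.07 (log2 ± SE, adjusted p = 0.00104, 5.33e-04 and 0.00658). Ren1 did not pass (log2 fold change 0.14 ± 0.15 (SE), adjusted p = 0.598). Of the matrix genes 0 of 39 were higher and 13 lower (0 and 25 adjusted over the list alone, camera adjusted p = 9.49e-17, and adjusted p = 0.0874 with an estimated correlation). They included Acta2, the smooth muscle actin of myofibroblasts, at -0.43 ± 0.06. Of the tubular injury genes 0 of 24 were higher and 4 lower (0 and 9 adjusted over the list alone, camera adjusted p = 1.38e-07). Of the fatty acid oxidation genes 11 of 30 were higher and 0 lower (15 and 0 adjusted over the list alone, camera adjusted p = 1.05e-13). They included Cpt1a at 0.40 ± 0.05. Of the clock genes 9 of 17 were higher and 3 lower (10 and 4 adjusted over the list alone, camera adjusted p = 4.86e-14). They included Dbp at 1.86 ± 0.11 and Per3 at 0.98 ± 0.08. Macrophage and monocyte genes gave 0 higher and 2 lower of 22 (0 and 10 adjusted over the list alone, camera adjusted p = 1.90e-08). Adrenal genes gave 2 higher and 0 lower of 5 (5 and 0 adjusted over the list alone, camera adjusted p = 7.53e-04). Kidney medulla genes gave 0 higher and 3 lower of 8 (0 and 6 adjusted over the list alone, camera adjusted p = 3.47e-05). With an estimated correlation these lists had adjusted p = 0.371.

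The count of the averaged captopril comparison depended on single libraries. It was 1471 without Control_water replicate 1, 523 without Control_water replicate 2, 571 without Control_water replicate 3, 598 without GN_captopril replicate 1, 575 without Control_captopril replicate 1, 620 without Control_captopril replicate 3 and 627 without GN_water replicate 3, against 952 with all 12 libraries. The interaction gave between 6761 and 7504 genes in the same test. The balance of directions turned as well. Captopril averaged gave 503 higher and 236 lower, 430 and 251, and 410 and 217 without GN_water replicates 1, 2 and 3, 756 and 715 without Control_water replicate 1, 439 and 437 without Control_captopril replicate 2, 513 and 430 with RLE size factors and 723 and 568 with DESeq2. The interaction gave 3511 and 3376, 3502 and 3292, and 3504 and 3361 without GN_water replicates 1, 2 and 3, 3578 and 3436 with DESeq2 and 1472 and 3858 with limma on RPKM.

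Genes that ranked among the 8 largest changes in either direction in the interaction or in a comparison of groups with different sex-linked markers mostly followed these markers. Besides Xist, the 4 Y-linked genes, Slco1a1 and Slc7a13, they included genes higher in the libraries with Xist. In Control_water, Control_captopril, GN_water and GN_captopril the means (n = 3 each) were 2.44, 1544, 946 and 1.34 CPM for Ugt1a2, a glucuronosyltransferase gene that shares exons with its neighbours, 0.285, 57.3, 72.7 and 0.780 for Hdc, which makes histamine, and 0, 5.82, 6.15 and 0.0953 for Myh1, a myosin of fast skeletal muscle. They were 1.17, 119.7, 48.3 and 0.472 for Igf2, a growth factor, 0.0572, 3.66, 1.77 and 0.0422 for its antisense transcript Igf2os and 0.0155, 3.27, 3.47 and 0.0239 for Atp13a4. For the transporter Slc17a2, the protease Tmprss6 and the galanin receptor Galr2 they were 0.257, 20.9, 20.0 and 0.401, 0.475, 21.3, 13.0 and 0.216, and 0.255, 2.25, 4.0 and 0.0643. Higher in the libraries with Y-linked transcripts were the major urinary protein genes Mup7 (16.4, 0, 0 and 5.39), Mup14 (9.62, 0, 0 and 3.78), Mup15 (9.93, 0, 0 and 1.21) and Mup19 (9.91, 0, 0.0987 and 1.96), which are near identical in sequence, Serpina1e (9.82, 0, 0.164 and 6.62) and Mpped1 (6.64, 0, 0 and 6.84). A mean of 0 allows up to 3 counts over a group. Mup7 lost its call in GN_captopril against GN_water without GN_captopril replicate 2, and in GN_captopril against Control_captopril also without Control_captopril replicate 1.

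With the sex-linked markers balanced, other genes ranked among the largest changes. In GN averaged, Cxcl13, a chemokine for B cells, had means of 0.0728, 0.370, 24.2 and 5.31 CPM in Control_water, Control_captopril, GN_water and GN_captopril (n = 3 each), and Clec4n, a lectin receptor of myeloid cells, changed by 5.79 ± 0.36 (log2 ± SE). Naaladl1 changed by -1.76 ± 0.38, the transcription factor Zbtb16 by -1.60 ± 0.39, Akr1b7 by -1.86 ± 0.66 and Ren2 by -1.48 ± 0.46. Fn1, which encodes fibronectin, changed by 0.83 ± 0.14 and the phosphate transporter Slc34a1 by -0.22 ± 0.06, while Ace (-0.19 ± 0.07, adjusted p = 0.0659) and Umod (-0.15 ± 0.09, adjusted p = 0.22) did not pass. In GN_water against Control_captopril, Fcrls changed by 6.76 ± 0.48, Ciart by -2.31 ± 0.43, and Cd5l, an apoptosis inhibitor of macrophages, had 10.6 against 0.0779 CPM. In GN_captopril against Control_water, the lower genes included Hspa1b (-2.11 ± 0.51), Banp (-1.79 ± 0.21), Bcl6 (-1.67 ± 0.26), Arntl (-1.66 ± 0.24), Npas2 (-1.45 ± 0.25) and Slc22a27 (0.0700 against 0.296 CPM). In captopril averaged, Hsd3b1 (0.0202, 27.2, 0.0165 and 10.4 CPM) and Cyp11a1 (0.0430, 9.82, 0.109 and 5.06 CPM), enzymes of steroid synthesis, and Star (4.85 ± 1.23) were highest in the libraries with adrenal marker counts. Ciart changed by 2.21 ± 0.26, Aim1l by 1.33 ± 0.19, Slc25a25, a mitochondrial carrier, by 1.32 ± 0.17, Psca by -2.29 ± 0.48, Igfbp2 by -1.54 ± 0.22, Rph3a by -1.52 ± 0.40, Sprr1a by -1.46 ± 0.28, the urea transporter Slc14a2 by -1.41 ± 0.37 and Npas2 by -1.28 ± 0.17.

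Calls of several of these genes depended on a single library, and no fold is given for genes with at most 3 counts in a group. In GN averaged the calls were lost for Akr1b7 without any 1 Control_water replicate, GN_captopril replicates 1 or 2, Control_captopril replicate 3, any 1 GN_water replicate (log2 -1.98 to -0.65) and Ren2 without Control_captopril replicates 1 or 2, GN_water replicates 2 or 3 (log2 -1.51 to -1.36), and gained for Ace without GN_captopril replicate 2, Control_captopril replicate 2, GN_water replicate 1 (log2 -0.27 to -0.22). Ace also passed with DESeq2, and Slc34a1 lost its call with limma on the deposited RPKM values and without both libraries with the most adrenal marker counts. In captopril averaged they were lost for Hsd3b1 without Control_water replicates 2 or 3, GN_captopril replicate 3, Control_captopril replicate 3, any 1 GN_water replicate, Cyp11a1 without any 1 Control_water replicate, GN_captopril replicate 3, Control_captopril replicate 3, any 1 GN_water replicate, Star without any 1 Control_water replicate, GN_captopril replicate 3, Control_captopril replicate 3, any 1 GN_water replicate (log2 2.68 to 5.08), Psca without Control_water replicate 2 (log2 -2.09), Rph3a without Control_water replicates 2 or 3, GN_captopril replicates 1 or 2, any 1 Control_captopril replicate, GN_water replicates 1 or 3 (log2 -1.65 to -1.16), Slc14a2 without Control_water replicates 2 or 3, GN_captopril replicates 1 or 2, Control_captopril replicates 2 or 3, GN_water replicates 1 or 3 (log2 -1.48 to -1.18) and Galr2 without Control_water replicates 2 or 3, any 1 GN_captopril replicate, GN_water replicates 1 or 2. In GN_water against Control_captopril they were lost for Star without Control_captopril replicate 3, any 1 GN_water replicate (log2 -6.04 to -1.25) and Akr1b7 without Control_captopril replicate 3, GN_water replicate 2 (log2 -3.52 to -1.11), and in GN_captopril against Control_water for Saa3 without any 1 Control_water replicate, GN_captopril replicate 3, Marco without any 1 Control_water replicate, GN_captopril replicate 3, Control_captopril replicate 3, Slc22a27 without any 1 Control_water replicate, GN_captopril replicates 1 or 2, Control_captopril replicates 2 or 3, any 1 GN_water replicate and Hspa1b without GN_captopril replicates 2 or 3 (log2 -2.12 to -2.0).

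**Figure D5:**
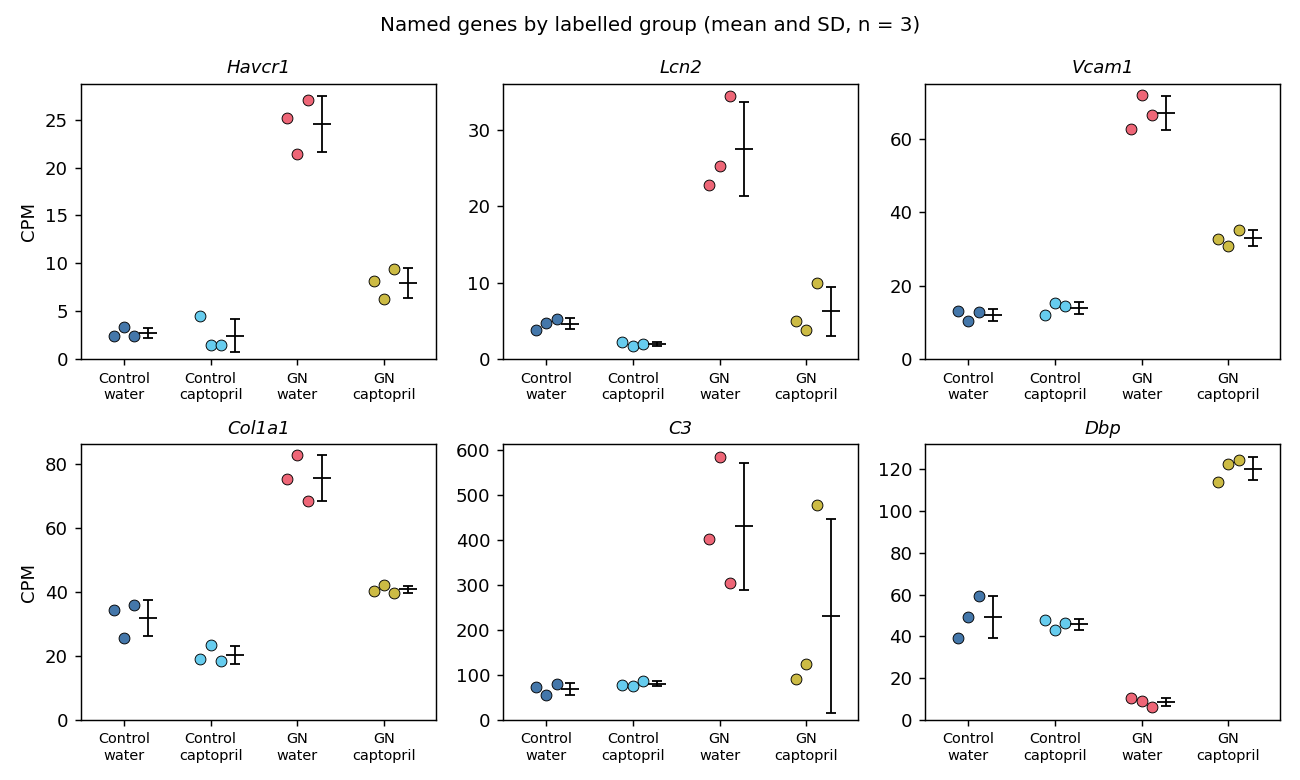
CPM of Havcr1, Lcn2, Vcam1, Col1a1, C3 and Dbp, 1 point per library with the group mean and SD (n = 3), groups as labelled. Lcn2 averaged 27.5 CPM in GN_water and 6.22 in GN_captopril, and Dbp 8.52 and 120.3 CPM.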

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

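The tests of Ren1, of the sex-linked markers, of the GN score other than the thinning of counts, and also the comparisons of groups with the same markers and the matching of symbols between tables were chosen only after the results were seen, while the outcomes expected of the splits and of the thinning were written before they were run.

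A difference between groups drew attention to 7406 genes in the interaction, which is the sex-marker contrast doubled. Another was of 952 genes in captopril averaged, which compares the GN effects of the marker-matched pairs. Of 100 splits (drawn from 200) that exchanged treatment labels within each disease state, only the real one called as many genes as the interaction. The highest other called 2698. The real split alone sets the markers fully apart, so its 7406 do not test a difference in the response to GN. For captopril averaged 6 of the 100 splits called as many as the real 952, the highest 7406, so chance cannot be excluded. These splits exchange libraries with different sex-linked markers, so those that mix the markers unevenly call genes through them, and the split with 7406 is the interaction itself. No split was run that keeps both markers and disease in balance. For GN averaged, only the real one of 100 splits within marker-matched pairs reached its 4516 (highest other 2492). This argues against chance labelling, not against other group differences. The 6 comparisons of 3 libraries with 3 have 10 splits each, too few for a share under 0.05. The real split called 7491 genes in GN_water against Control_water, 6594 in GN_captopril against GN_water, 4731 in Control_captopril against Control_water, 5813 in GN_captopril against Control_captopril, 4406 in GN_water against Control_captopril and 1765 in GN_captopril against Control_water, and each other split 0.

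Ren1 also differed between groups, by 8.61 on the log2 scale in the interaction. Ren1 was 17.9 times as high in Control_water as in Control_captopril, although captopril is known to raise it. Its GN effects in the marker-matched pairs were alike. Ren2 counts were at most 0.622% of Ren1 counts in a group, but C57BL/6 mice lack this paralog, so the value does not test whether reads were shared. An exchange of the treatment labels of the control groups and a difference between the sexes cannot be told apart here, because the groups differ in both. With the sex-linked markers balanced, the Ren1 difference between the treatment labels was 0.14 ± 0.15 (log2, SE), so a candidate explanation in which Ren1 follows the sex-linked markers stays open, as does one in which labels were exchanged.

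Xist without Y-linked transcripts in 6 libraries labelled male conflicted with those labels. RNA of both sexes mixed in a library is argued against, since the weaker marker reached at most 0.0786% of its mean in the libraries that carry it. Female mice labelled male may be the explanation: the 8 androgen-induced kidney genes had a median log2 ratio of 4.71 between the libraries with Y-linked transcripts and those with Xist. The 4 female-biased genes went both ways, 2 higher and 2 lower (Cyp2a4 and Cyp2a5) in the libraries with Xist, and that list was not called (camera adjusted p = 0.289 in Control_captopril against Control_water and 0.47 in GN_water against Control_water), though without GN_captopril replicate 3 it was called upward in both (0.00159 and 0.0297), so that outcome rests on 1 library. Whether the mice, the tubes or the labels were exchanged was not tested, and neither was a true difference in the animals used for each group.

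The GN score rose less from Control_water to GN_captopril than from Control_captopril to GN_water, a difference between groups of -0.51, and it was lower in GN_captopril than in GN_water by -0.48. A constant offset between the sexes as the only cause is argued against, since the score of Control_captopril minus Control_water was -0.0361. The control groups also differ in treatment label, so an offset hidden by an opposite treatment effect cannot be told from none. Library size is argued against, since thinning every library to the smallest total left -0.470 (mean of 20 draws, SD 0.00109). A weaker response to GN in 1 sex, at -0.51, and captopril treatment, at -0.48, cannot be told apart, because each GN group carries only 1 set of sex-linked markers. Genes from GN_captopril against Control_captopril gave 0.84, but they were chosen on 1 of the groups compared, which favours a higher score there. They were also chosen between groups with different sex-linked markers.

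Among 137 symbols of the RPKM table that have no entry of that name in the count table and passed the RPKM minimum, 21 were higher and 9 lower in GN averaged (limma, adjusted p under 0.05). Of the 137, 132 had RPKM values proportional to the counts of 1 gene listed under another symbol (coefficient of variation of the ratio over the libraries at most 0.00834, against at least 0.0263 for the next best of 331 genes compared), among them all 21 higher and 8 of the 9 lower. These genes were therefore part of the comparisons of counts, where 16 of the 21 were also called higher and 8 of the 8 lower.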

How the results depend on the processing

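The alternatives for both comparisons of groups with the same sex-linked markers, and the setting without both libraries with the most adrenal marker counts, were chosen after the data had been seen. Each count of genes changed stayed within 1.5 times its value under RLE size factors, either count filter, DESeq2, the robust fit and the title-number block. The block was not part of the fits reported because libraries with the same number were not alike (mean correlation 0.0177 over 18 pairs, range -0.235 to 0.236, 0 libraries most alike to their own number), and with it GN averaged gave 4684 genes. A minimum absolute log2 fold change of 1 lowered the counts by construction, to 1945 (GN_water against Control_water), 1031 (GN_captopril against GN_water), 720 (Control_captopril against Control_water), 1266 (GN_captopril against Control_captopril), 2650 (interaction), 813 (GN averaged), 39 (captopril averaged), 1158 (GN_water against Control_captopril) and 450 (GN_captopril against Control_water). Limma on log2 RPKM with pseudocounts of 0.5 and 0.1 gave 4713 and 4708 (GN_water against Control_water), 2142 and 2151 (GN averaged), 2342 and 2315 (GN_water against Control_captopril), and 930 and 955 (GN_captopril against Control_water, 1021 without a filter), and the cause was not tested. That last count was also 951 with only its 6 libraries in the fit and 938 without both libraries with the most adrenal marker counts, for which the cause was not tested. Leaving out 1 library gave 6692 to 7661, 5440 to 6935, 3863 to 4885, 4830 to 6182, 6761 to 7504, 3907 to 4564, 523 to 1471, 3237 to 4855 and 968 to 1708 genes in the order of the fold minimum. Captopril averaged gave 1471, 523 and 571 without Control_water replicates 1, 2 and 3, 598 without GN_captopril replicate 1, 575 and 620 without Control_captopril replicates 1 and 3 and 627 without GN_water replicate 3. GN_captopril against Control_water gave 975 without Control_water replicate 2 and 968 without GN_captopril replicate 3. The cause was not tested. With an estimated correlation, 5, 6, 3, 4, 3, 12, 3, 11 and 8 lists were called in that order, against 24, 18, 7, 17, 13, 24, 14, 24 and 23 with the preset one, and the cause was not tested. Leaving out 1 library gave 22 to 25, 17 to 22, 6 to 9, 17 to 20, 12 to 14, 23 to 24, 14 to 19, 24 and 20 to 24 lists. The GN score difference of GN_captopril and GN_water turned to 0.84 with genes from GN_captopril against Control_captopril, was -1.15 with genes from GN_water against Control_water, each set being chosen on 1 of the groups compared, which favours a higher score there, and ran from -0.605 to -0.358 over the left-out libraries. Among 4896 list results under alternatives 4646 kept their call and direction, 154 lost and 96 gained one. Among 20728 results of named genes 19784 kept them, 857 lost and 86 gained a call, and 1 turned: Agtr1a in the interaction, at -0.0103 with limma on RPKM, for which the cause was not tested. RLE in place of TMM moved the median log2 fold change of all genes by no more than 0.0294. Depth limits genes at few counts: 3 counts over a group correspond to 0.0452 to 0.0635 CPM, and GN_captopril, with the lowest totals, has the highest floor.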

Other observations

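Clock genes differed between the groups. Npas2 was lower in both captopril groups, and the others given here followed neither disease nor treatment label alone. Dbp averaged 49.3 ± 9.94 CPM in Control_water, 45.8 ± 2.60 in Control_captopril, 8.52 ± 2.07 in GN_water and 120.3 ± 5.63 in GN_captopril (SD, n = 3 each). Arntl, which encodes the activator BMAL1, averaged 13.5 ± 2.53, 12.4 ± 4.03, 20.3 ± 2.21 and 4.22 ± 1.05 CPM in the same order, opposite to Dbp in the GN groups. Ciart, a repressor of the clock, averaged 1.62 ± 0.385, 1.30 ± 0.422, 0.252 ± 0.0915 and 7.03 ± 2.57 CPM, Per3 19.0 ± 0.922, 13.7 ± 2.23, 4.56 ± 0.347 and 24.8 ± 2.57, and Npas2, a partner of BMAL1, 11.2 ± 1.61, 5.38 ± 0.716, 11.7 ± 1.60 and 4.04 ± 1.84. The labels do not give the hour of collection.

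Genes of other kinds also differed between the libraries with Y-linked transcripts and those with Xist. Prlr, the prolactin receptor, averaged 290.1 ± 43.2 CPM in Control_captopril and 282 ± 14.5 in GN_water against 12.2 ± 3.18 in Control_water and 19.0 ± 10.5 in GN_captopril (SD, n = 3 each). Slc7a12, an amino acid transporter, averaged 298 ± 61.1 and 295 ± 36.0 against 10.7 ± 4.30 and 16.5 ± 9.03 CPM. Cyp2a4, a steroid hydroxylase in the list of female-biased genes, went the other way, with 315 ± 19.4 and 306 ± 52.8 against 809 ± 118 and 777 ± 59.3 CPM.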
